A study of Homo sapiens with 6 samples.

How the data were processed

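Total RNA of THP-1 cells was hybridised after biotin labelling to 1-colour arrays, 3 for cells treated with GSK126 and 3 for control cells. Groups were taken from the treatment label of each sample, and replicate numbers from the titles. The only data used here were the deposited value table, which gives 1 log2 expression value per probe set and array. Per the submitters' processing notes, the authors used RMA and Partek, whose versions and options were not given in the sources used here. RMA corrects the background, normalizes arrays by quantiles and summarizes probes on the log2 scale. The log base was not written in the table and was taken from RMA and from the range of the deposited log2 values, 0.97 to 13.8. The arrays did not share 1 distribution of probe set values. RMA normalizes probes before it summarizes them, so this does not settle whether another step was applied. The values were not centred on each probe set. No column belonged to a sample outside the 6.

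The platform annotation was matched to the table by identifier. Of 32321 identifiers, 18889 had 1 gene symbol, 1589 had several and 11843 had none. Symbols were updated through the gene number with a RefSeq gene table of the current human assembly, in which 18859 of the 18889 were matched and 0 symbols changed. For gene-level tests the probe set with the highest mean represented each of 18186 genes.

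Differences were tested on the deposited log2 values without further normalization or filtering, with lmFit and eBayes of limma 3.58.1 in R 4.3.3. The tests were two-sided, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. With 3 arrays against 3, an exact permutation test of a single value cannot give a p below 0.1, so none was used for single probe sets. Of 38 gene lists, the 37 with at least 5 measured genes were tested with camera (preset correlation of 0.01) and adjusted over those 37. The level of a list was set against 10000 random lists of the same size.

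On simulated data with 200 changed probe sets among 32321 and the spread of the real GSK126 and control arrays, the test recovered 0% of changes of 1.5-fold and 0% of 2-fold, and 76.5% of 4-fold, with 2 false calls among 155. A simulated shift of 1 list was called, and 0 of 36 lists that shared no member with it were called. The simulated genes varied independently, so this does not show how often camera calls an unshifted list in the real data.

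The design, the gene lists, the alternatives and the rule for named items were fixed before the data were examined. The rule named EZH2, EZH1, EED and SUZ12, then among probe sets with 1 symbol, past the threshold and with groups that did not overlap, the 12 with the largest increase and the 12 with the largest decrease, and up to 4 members of each list that shifted. Loci without a protein-coding style symbol were skipped. Since the levels did not bear out the annotation, none of these genes is reported by name, and only the first 2 identifiers in each direction are given. Alternatives tried were quantile normalization, median-centring, leaving out dim probe sets, an intensity trend with robust moderation, no moderation, array weights, the replicate number as a block, each array left out in turn, other thresholds and other ways to represent a gene. Leaving out both arrays numbered 2 together, or the first 4088 probe sets of the table, was added after the data had been seen.

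Whether identifiers and values were out of step was examined with a hidden Markov model written in Python 3.11.15 with numpy 2.4.6, chosen after the data had been seen. It let each identifier's value stand a number of places earlier in the table, up to 1200, with that number growing by 1 wherever an identifier had no value, at a preset share of 0.03. The model used only the mean level over all 6 arrays, the spread within groups and the class of the symbol (housekeeping, tissue-restricted, small RNA, zinc finger, several symbols or none), and no difference between the groups. The fit with the highest likelihood of 3 starts was kept. An earlier alignment by dynamic programming lost its track along the table, and an earlier fit with 1 start did not settle when only part of the symbols was used, so both the model and the number of starts were settled after seeing earlier results. In 3 simulated tables the model placed 73.2% to 76.5% of identifiers exactly, and 97.2% to 99.2% of those with a posterior probability of at least 0.9. Their levels were drawn from the model's own symbol classes, with 800 identifiers removed at random. These percentages therefore do not measure the accuracy of the placement in the real table.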

Results

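Gene expression was measured on 6 arrays in THP-1 cells, a human monocytic leukaemia cell line, with and without GSK126, a small-molecule inhibitor of the histone methyltransferase EZH2. EZH2 is the catalytic subunit of Polycomb repressive complex 2 (PRC2), which places a repressive methyl mark on histones. There were 3 arrays of treated cells and 3 arrays of control cells. The labels disagreed on the dose, since the sample sources gave 10 µM and the treatment protocol gave 2 µM for 24 h, so no dose is attached to the values. The compound number in the sources also ran up by 1 from one treated sample to the next, whereas every description named GSK126. No label said whether the 3 samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The number of arrays limited the precision of every value.

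The values were log2 expression levels of 32321 probe sets, with array medians between 4.80 and 5.12. Every pair of arrays correlated with r between 0.932 and 0.989 across probe sets, which are not independent replicates. The arrays numbered 2 stood apart in both groups. Their SD over probe sets was 1.96 in the GSK126 group and 1.86 in the control group, against 2.08 to 2.17 on the remaining arrays. Their interquartile ranges of 2.73 and 2.58 were also narrower than the 3.02 to 3.14 of the others. No pair of arrays shared more than 0.170% of its values exactly.

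**Figure D1:**
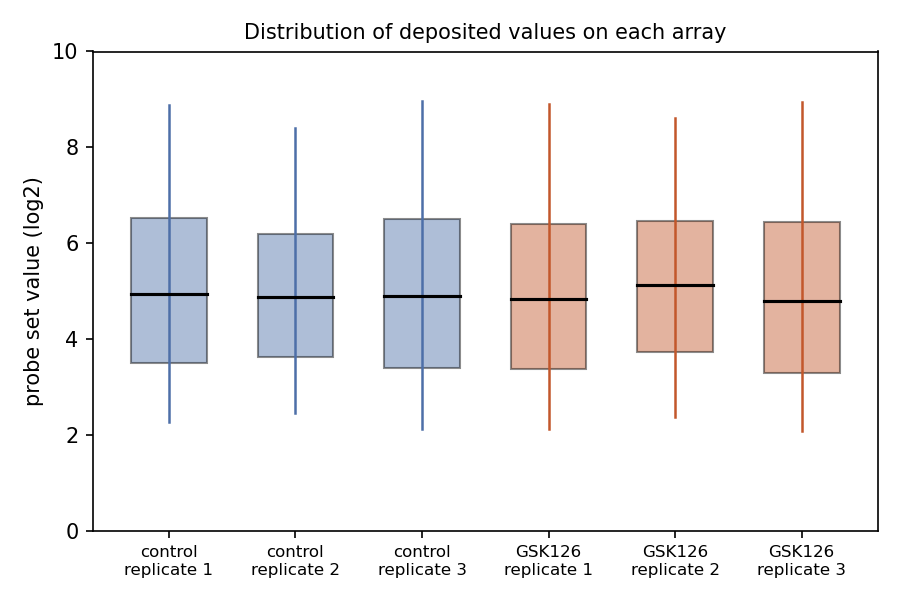
Values of all probe sets on each array, on the log2 scale, with the median (line), quartiles (box) and 5th to 95th percentiles (whisker) for the control arrays (blue) and the GSK126 arrays (orange). The arrays numbered 2 have the narrowest boxes in both groups, with interquartile ranges of 2.58 (control) and 2.73 (GSK126).

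The comparison of treated with control cells asked which transcripts responded to inhibition of EZH2. With GSK126, 421 probe sets differed at an adjusted p under 0.05 in limma's moderated test with Benjamini-Hochberg adjustment. Of these, 329 were higher and 92 were lower, so that 78.1% of the changes were increases. The median log2 difference was 1.71 among the increases and -1.60 among the decreases, and the smallest called difference was 0.94. At least a 4-fold difference was seen in 118 of the increases and 21 of the decreases, and at least an 8-fold difference in 26 and 2 of them. The probe sets that rose lay near the middle of the array in control cells, with a median level of 5.42 against 4.91 over all probe sets, and reached 7.40 with GSK126. Those that fell started higher, at a median of 7.45 in control cells, and reached 5.79. Only 20 of the 329 increases started below the lower quartile of all probe sets, 3.49, and 7 of the 92 decreases ended below it.

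**Figure D2:**
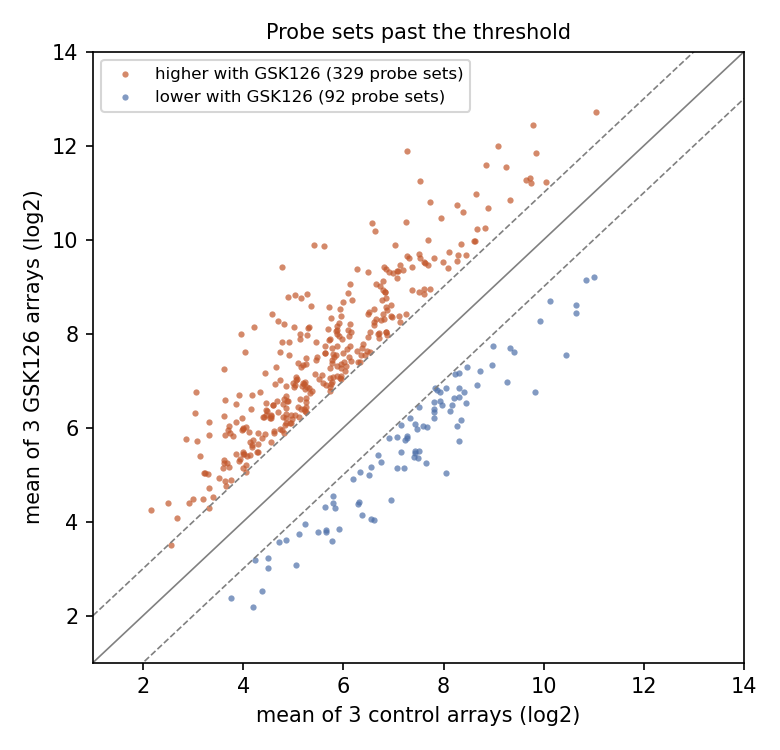
Mean log2 level of each called probe set in 3 GSK126 arrays (vertical axis) against 3 control arrays (horizontal axis), with 329 higher in orange and 92 lower in blue. The solid line marks equal levels and the dashed lines a 2-fold difference, which 327 of the increases and 91 of the decreases reached.

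All 421 called probe sets had 3 GSK126 values that did not overlap the 3 control values. Without regard to the test, 4778 probe sets (14.8%) had groups that did not overlap, where chance gives 10%. Two-sided p-values under 0.05 before adjustment were found for 3261 probe sets. The probe set 8120992 had the largest increase among those eligible by the rule for named items. It rose from 4.76 ± 0.35 to 9.42 ± 0.46 (SD, n = 3), a log2 difference of 4.65 with a standard error of 0.29 and a limma adjusted p of 0.00091. The probe set 8124994 rose from 7.27 ± 0.52 to 11.9 ± 0.56 (SD, n = 3), by 4.61 with a standard error of 0.34 (limma, adjusted p = 0.0015). In the other direction, the probe set 8096808 went from 10.5 ± 0.64 to 7.55 ± 0.46 (SD, n = 3), a difference of -2.90 with a standard error of 0.35 (limma, adjusted p = 0.0074). The probe set 8063478 went from 8.31 ± 0.59 to 5.72 ± 0.27 (SD, n = 3), a difference of -2.60 with a standard error of 0.31 (limma, adjusted p = 0.0067). The lowest called difference, -3.06, was that of a probe set not eligible by the rule, which relies on annotated symbols. The count of called probe sets depended on the samples, the scaling and the probe sets tested: it was 141 without GSK126 replicate 1, 102 without GSK126 replicate 3, 238 without control replicate 1 and 206 without control replicate 3; without both arrays numbered 2 it was 1738, of which 852 were higher and 886 lower, and it was 799 (569 higher, 230 lower) without the first 4088 probe sets of the table. Quantile normalization of the deposited values gave 672 calls (434 higher, 238 lower), median-centring 195, array weights 4811 (1917 higher, 2894 lower) and a model without moderation 0, with 2878 probe sets at an unadjusted p under 0.05. With the replicate number as a block the count was 222 (188 higher, 34 lower). The first 4088 probe sets, left out after the data had been seen, varied more between replicates. Their median SD was 0.51, against 0.27 over the later probe sets. Of these first probe sets 0.27% were among the 421 calls, against 1.45% of the later ones.

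The changed probe sets are given by identifier because their levels did not bear out the genes that the platform annotation attaches to the identifiers. The identifiers mark places in the table, and the values given beside them may belong to other probe sets. Under that annotation the genes of cytosolic ribosomal proteins, which are abundant in all growing cells, had a median level of 5.49 over 32 genes. Random lists of 32 genes had medians between 4.06 and 5.83 in the central 95%. Oxidative phosphorylation genes, also needed in every cell, had a median of 5.77, below the median of 5.96 of neuronal markers and that of B cell markers, 5.97. The probe set annotated to GAPDH, a glycolytic enzyme, was at 4.11 ± 0.10 in control cells (SD, n = 3), at the 36.3rd percentile of all probe sets, and that of ACTB, a cytoskeletal actin, at 6.08 ± 0.58 (SD, n = 3) and the 71.0th percentile. That of LYZ, the lysozyme that monocytes secrete, was at 3.20 ± 0.29 (SD, n = 3), whereas that of HBB, a globin of red cells, was at 9.86 ± 0.61 (SD, n = 3) and the 98.1st percentile. These 4 genes were chosen as checks of the annotation outside the rule for named items. None of the 37 gene lists with at least 5 measured genes had a median above the central 95% of random lists, and 1, fatty acid synthesis and SREBP1 targets, lay below it at 3.27.

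**Figure D3:**
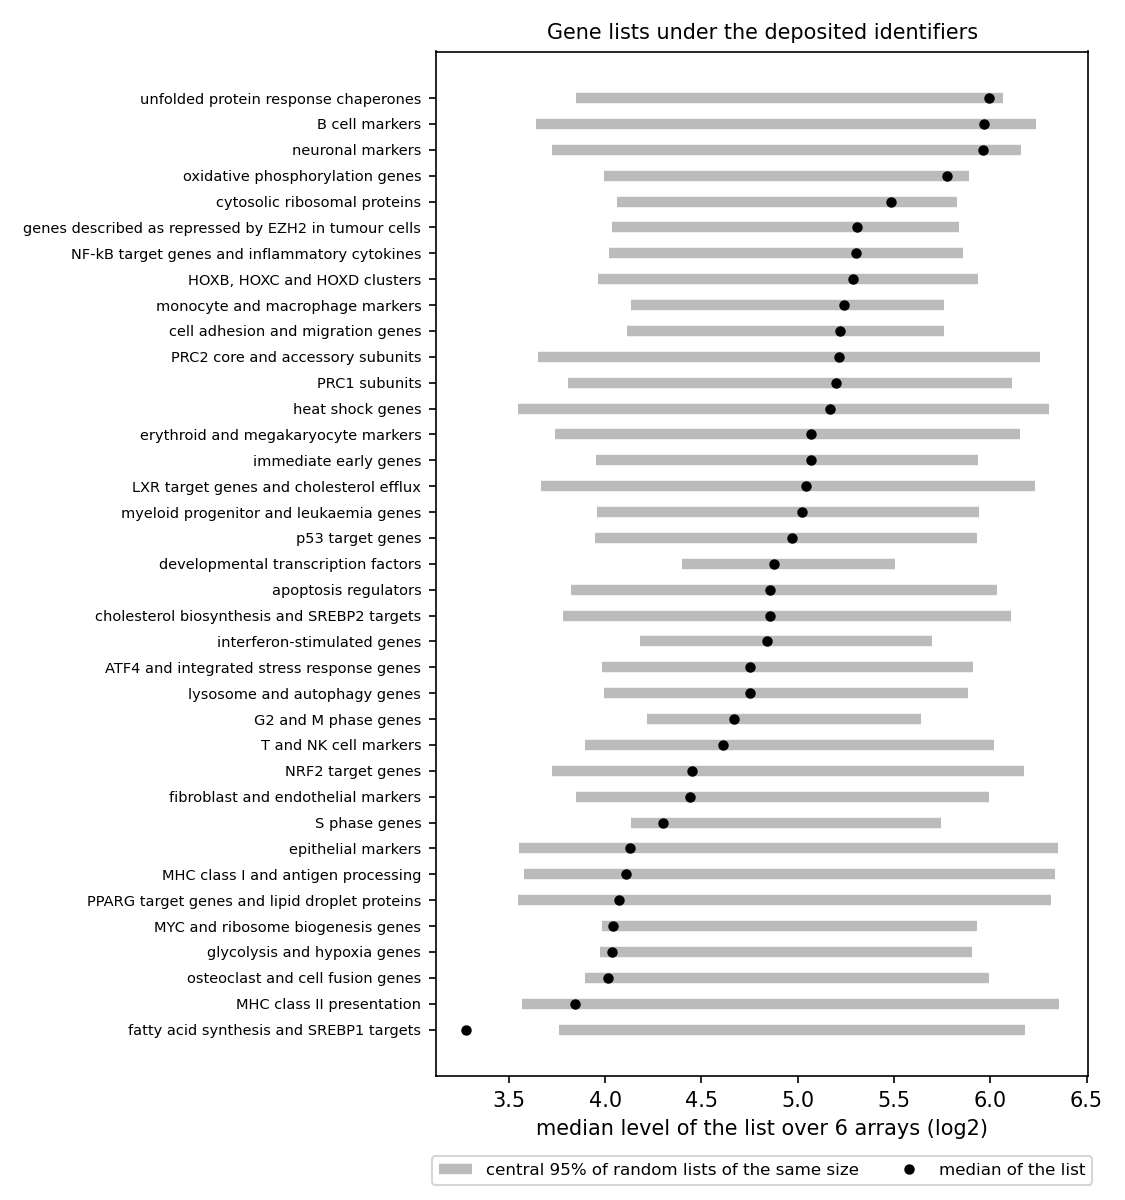
Median log2 level over 6 arrays of each of 37 gene lists under the deposited identifiers (points), with the central 95% of the medians of 10000 random lists of the same size (grey bars). Ribosomal proteins lie at 5.49 and neuronal markers at 5.96, both inside the range of random lists, and only fatty acid synthesis and SREBP1 targets lie outside.

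The lists fixed in advance covered Polycomb subunits and targets, the cell cycle, lipid metabolism, immune and stress responses, myeloid identity and markers of other cell types. Under the deposited identifiers none of the 37 lists shifted with GSK126 by limma's camera test. The adjusted p-values ran from 0.84 to 0.97, and 0 lists had an unadjusted p under 0.05. The median log2 difference of a list lay between -0.13 and 0.12. Neither camera with an estimated correlation nor fry called a list, with 0 calls each. The 14 probe sets annotated to PRC2 subunits included 0 past the threshold in limma's test over all probe sets, and 4 had an unadjusted p under 0.05. Of the same 14, 1 passed when adjusted over genes and 1 when adjusted over the list alone. Because the annotation was not borne out by the levels, these results describe the identifiers and not the expression of EZH2, its partners or the genes of any list.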

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

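Leaving out both arrays numbered 2 together and leaving out the first probe sets of the table were chosen after seeing the data, as were all alternatives for the realigned lists; the others were planned. The 421 calls became 672 with quantile normalization, 195 with median-centring, 4811 with array weights (estimated without convergence), 740 at an adjusted p of 0.10, 1738 without both arrays numbered 2, 799 without the first 4088 probe sets and 0 without moderation. Leaving out 1 array gave 102 to 501. Of the 421, 379 were also called after quantile normalization, 410 without both arrays numbered 2 and 421 with array weights. Leaving out dim probe sets, the trend with robust moderation and both ways to represent a gene stayed within 1.5 times of 421. A 1.5-fold minimum could remove none of the 421, since the smallest called log2 difference was 0.94. Of the 14 PRC2 identifiers, 1 was called after quantile normalization, 6 with array weights and 3 without both arrays numbered 2, against 0 (1 when adjusted over genes); the cause was not tested for any of these. The lists under the deposited identifiers gave 0 calls in every alternative run. The 4 named probe sets kept direction and call in 51 of 56 alternative values; all 4 lost the call without moderation (adjusted p 0.14 to 0.23). Same-numbered deviations correlated at -0.01, 0.16 and 0.19, and 4 of 6 arrays correlated best with their own number. All correlations of deviations between the groups lay between -0.18 and 0.19. These values do not settle whether the replicate number pairs the samples. With that number as a replicate block, 222 probe sets were called, 211 of them among the 421, and the call of 8096808 was lost (adjusted p = 0.053). Of 255 alternative values of the 17 realigned lists, 226 kept their call, 29 did not and 0 changed direction; 16 of the 29 came from the estimated correlation.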

Other observations

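The tests of the identifiers, of random placement and of the arrays numbered 2 were chosen after the levels had been seen, whereas the test of neighbouring probe sets and both counts of splits were set out before their results. The pattern was that genes needed in every cell were not high under the deposited identifiers. Outdated names alone would leave identifiers and values in step. The spread between replicates dropped, from a median SD of 0.51 to 0.27, 115 places before the first named identifier. Identifiers without a symbol also occurred later in the table, so such probe sets could fill those places. The gap alone therefore cannot exclude outdated names. A candidate explanation is that identifiers and values are out of step by a number of places that grows along the table. Under the deposited identifiers the difference between housekeeping and tissue-restricted symbols was 0.13 over all of these symbols. With offsets fitted on one random part of the symbols, the difference among those of the remaining part was 1.93. In 1000 random displacements it was at most 0.41. The reverse fit gave 1.87 against at most 0.39. Hybridization that failed altogether would leave no such difference at any placement, so these values argue against it as the whole cause. Degraded RNA could weaken such a difference but would not move it to other places of the table. The rise from 0.13 to 1.93 and 1.87 therefore also argues against degradation as the whole cause of the pattern. No measure of RNA quality was examined, so the quality of the RNA itself stays open.

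If that hypothesis holds, the lists can be read at the realigned places, which were fitted without any difference between the groups. The fitted offset grew from 132 to 822 places, and the log-likelihood gain was 1198, against at most 99.1 in 5 shuffled tables. Fits on the separate parts of the symbols agreed on the exact place for 44.3% of identifiers and within 10 places for 86.2%. The posterior was at least 0.9 for 58.6% of identifiers. Identifiers that the model left without a value still took a place, so some list members may carry a neighbour's value. Lists are therefore described and no single gene is named. Ribosomal proteins then had a median level of 10.4. Of the markers of other cell types, those of T and NK cells (4.26), fibroblasts and endothelium (4.11) and neurons (3.99) lay below the central 95% of random lists, and those of B cells (4.73), epithelium (4.89) and the erythroid and megakaryocyte lines (5.11) lay inside it. By camera with the preset correlation, 17 of 37 lists shifted with GSK126, 14 up and 3 down. With an estimated correlation 1 of the 17 kept its call, NF-kB targets (adjusted p = 0.049), and the other 16 had adjusted p-values from 0.052 to 0.65. Interferon-stimulated genes had the largest shift: the mean of 44 members went from 5.10 ± 0.11 to 6.67 ± 0.22 (SD, n = 3), a difference of 1.57 (limma camera, adjusted p = 1.88e-41, and adjusted p = 0.052 with an estimated correlation). Of these members 26 were higher over all probe sets, 33 passed when adjusted over the list alone, and 0 were lower. NRF2 targets, the oxidative stress response, were higher by 1.24 (8 of 17 members called). NF-kB targets were higher by 0.96 (10 of 31 higher, 1 lower), immediate early genes by 0.77 (5 of 26) and ATF4 targets by 0.67 (4 of 29). Osteoclast and cell fusion genes differed by 0.59 (median 0.30), lysosome and autophagy genes by 0.53, LXR targets by 0.51, fatty acid synthesis by 0.46, adhesion and migration genes by 0.46 and cholesterol biosynthesis by 0.33. Monocyte and macrophage markers differed by 0.42 (median 0.23), with 7 of 40 higher and 3 lower. Genes described as repressed by EZH2 in tumour cells differed by 0.31 in the mean and 0.08 in the median, with 3 of 32 higher, so few members carried the mean. S phase genes were lower, from 6.59 ± 0.22 to 5.88 ± 0.10 (SD, n = 3), a difference of -0.71 (limma camera, adjusted p = 4.7e-19, and adjusted p = 0.24 with an estimated correlation). Of its 40 members 4 were lower over all probe sets and 29 passed when adjusted over the list alone. G2 and M phase genes differed by -0.41 with 0 of 52 members called over all probe sets and 10 when adjusted over the list alone. Myeloid progenitor and leukaemia genes differed by -0.51 (median -0.18) with 5 of 27 lower, and 7 passed when adjusted over the list alone. Unfolded protein response chaperones, at 0.31, were the 1 called list whose groups overlapped.

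The size of several shifts depended on the placement. With offsets from the first part of the symbols alone, NRF2 targets differed by 0.69, NF-kB targets by 0.46 and immediate early genes by 0.40. With those offsets 5 lists lost their call: monocyte and macrophage markers (difference 0.16, adjusted p = 0.38), ATF4 targets (0.21, adjusted p = 0.24), lysosome and autophagy genes (0.22, adjusted p = 0.054), cholesterol biosynthesis (0.25, adjusted p = 0.066) and unfolded protein response chaperones (0.23, adjusted p = 0.051). With offsets from the second part, monocyte and macrophage markers (0.22, adjusted p = 0.25) and the chaperones (0.18, adjusted p = 0.13) lost theirs, and fatty acid synthesis differed by 0.29. At places with a posterior of at least 0.9, LXR targets lost their camera call (difference 0.44, adjusted p = 0.087), and genes described as repressed by EZH2 differed by 0.49. By fry 6 of the 17 were called: interferon-stimulated genes, NF-kB targets, immediate early genes, NRF2 targets, S phase genes, and osteoclast and cell fusion genes. Fry also called MHC class II genes (adjusted p = 0.046), which camera did not call (adjusted p = 0.33). Genes described as repressed by EZH2 lost their camera call without GSK126 replicate 2 (difference 0.26, adjusted p = 0.11) and without both arrays numbered 2 (0.23, adjusted p = 0.072). Cholesterol biosynthesis lost its camera call without GSK126 replicate 3 (0.27, adjusted p = 0.089). Unfolded protein response chaperones lost theirs without GSK126 replicate 3 (0.27, adjusted p = 0.057) or control replicate 2 (0.12, adjusted p = 0.26). Without control replicate 2, cholesterol biosynthesis differed by 0.19. The remaining 20 lists were not called by camera. Among them PRC2 subunits differed by -0.22, PRC1 subunits by -0.06, developmental transcription factors by 0.01, the HOXB, HOXC and HOXD clusters by 0.03, p53 targets by 0.06 and PPARG targets by 0.34. Without both arrays numbered 2, developmental transcription factors (-0.17), the HOXB, HOXC and HOXD clusters (-0.08) and p53 targets (-0.03) turned below 0. PRC2 subunits (-0.26), PRC1 subunits (-0.09) and PPARG targets (0.28) kept their direction. MHC class I genes differed by 0.0054, heat shock genes by 0.21, glycolysis and hypoxia genes by 0.08, oxidative phosphorylation by -0.04, apoptosis regulators by 0.11, MYC and ribosome biogenesis genes by -0.14 and ribosomal proteins by -0.12. Without both arrays numbered 2, MHC class I genes (-0.20), glycolysis and hypoxia genes (-0.07) and apoptosis regulators (-0.01) turned below 0. Oxidative phosphorylation (-0.23), MYC and ribosome biogenesis genes (-0.20), ribosomal proteins (-0.41) and heat shock genes (0.14) kept their direction. Markers of T and NK cells differed by -0.05, of B cells by 0.04, of the erythroid and megakaryocyte lines by -0.09, of epithelium by 0.04, of fibroblasts and endothelium by 0.0006 and of neurons by 0.07. All of these marker lists lay below 0 without both arrays numbered 2, from -0.01 (fibroblasts and endothelium) to -0.26 (erythroid and megakaryocyte lines). MHC class II genes had a mean difference of 0.47 and a median of -0.04, and the mean and median also differed in sign for the HOXB, HOXC and HOXD clusters, p53 targets, fibroblast, B cell and neuronal markers. For MHC class I genes and fibroblast markers camera, which compares a list with all other genes, pointed down although the mean difference was above 0. The HOXA list had 1 measured gene and was not tested.

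For the rise of interferon-stimulated genes and the fall of S phase genes at the realigned places, random placement of the identifiers was tested by moving the places by 20 to 500 at random. For both lists the p was 0.001, the smallest that 1000 displacements can give. All 17 called lists passed this test after adjustment, although some displacements gave larger differences for unfolded protein response chaperones and cholesterol biosynthesis. Like camera, the test set a list's difference against that of other places on the same arrays. It is therefore not separate support for the 17 calls. PPARG targets and MHC class II genes, which camera did not call, also passed the displacement test (adjusted p = 0.023 each). Without both arrays numbered 2, the interferon difference was 1.64 and both lists kept their calls at the preset correlation, which argues against those arrays as the cause. Camera with all arrays and an estimated correlation called neither (adjusted p = 0.052 and 0.24). By fry, which does not compare a list with other genes, both were called (adjusted p = 0.0033 and 0.046). An effect of GSK126, which the design names, stays open and may account for these shifts, as does any unrecorded difference between the 2 sets of arrays. The number of called lists does not by itself set the real groups apart: 3 of the 10 splits of the 6 arrays, the real one included, gave at least 17 lists, and the highest other split gave 22. The third of these splits gave 20. Both of these other splits kept the arrays numbered 2 on the same side and also kept GSK126 replicates 1 and 3 together. Every split other than the real one mixes the groups unevenly and so holds part of the real difference, which does not single these out. The split of GSK126 replicates 1 and 3 with control replicate 2 also kept those replicates together and gave 12 lists. The remaining splits with the arrays numbered 2 on the same side gave 13 and 11 lists, and the splits other than the real one that parted them gave 2 to 12.

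For the count of changed probe sets, 1 of the 10 splits, the real one, gave as many as 421, and the highest other split gave 0, with up to 3080 unadjusted p-values under 0.05. Splits of 3 against 3 are too few for a share under 0.05. A further hypothesis was that probe sets next to each other in the table respond together, which would be seen as a correlation between neighbouring log2 differences above that of every other split. The correlation was 0.079 with the real groups and 0.085 in the highest other split, so the real groups did not stand above every other split. That split joined GSK126 replicates 1 and 3 with control replicate 1 and, like every other split, held part of the real difference. The comparison therefore cannot decide the question.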
